A study of Mus musculus with 13 samples.

How the data were processed

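Bulk RNA sequencing was made from the arcuate nucleus of 13 mice, a hypothalamic region that holds the AgRP and POMC neurons. Per the labels, total RNA was extracted with Trizol and libraries were made with the Takara SMART-Seq Ultra Low Input kit. The mice were knockouts (KO), in which Cre recombinase under Agrp deletes a floxed Klf4 gene, or control littermates. They were fed regular chow or a high-fat diet (HFD) for 10 weeks, and were 20 weeks old at collection. The groups were KO on HFD (n = 3), controls on HFD (n = 4), KO on chow (n = 3) and controls on chow (n = 3), taken from the sample titles, which also give each mouse a sex letter. Replicate numbers follow accession order and only name a library. In the titles, KO_HFD replicate 2 and the library labelled Control_HFD replicate 3 share a mouse number with different suffixes, as do Control_HFD replicates 1 and 2, and what a shared number marks is not given in the labels. Library batches are not given in the labels, and the mouse numbers in the titles fall in different series for chow and HFD, so diet and any batch that follows these numbers cannot be separated. Whether the control mice carried Cre, and which Agrp-Cre line was used, is not given in the sources used here.

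The authors deposited 1 table with a raw read count per gene and library and the matching RPKM for 55421 gene identifiers. STAR, STAR-Fusion, Subread, FastQC, edgeR and the mouse build mm10 are named in the submitters' processing notes, without versions or roles. The annotation release, the strand setting of the counting and the read filters are not given in the sources used here. The deposited RPKM equalled the count scaled per kilobase and per M counts, that is, divided by the column total and by the length plus 1 base, to within 5.6e-16 relative difference. RPKM was therefore not tested, and every test used the deposited counts.

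Of the 55421 identifiers, 54673 occur with the same version in GENCODE M21, 53159 of these with the same symbol, and all 54673 have the same gene start. Coordinates below are from that annotation, which uses the same assembly as mm10 (GRCm38). The deposited end column lay below the annotated gene end for 32704 identifiers and was not used. There were 113 symbols shared by more than 1 identifier, and 14646 identifiers had no read in any library. Because strand was not stated, reads of overlapping genes on opposite strands cannot be told apart. The annotated model of Agrp spans 70.7 kb and overlaps neighbouring genes, so its count can hold their reads.

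Counts summed to between 34.7 and 68.2 M per library. Control chow libraries held 34.7 to 43.5 M, KO chow libraries 37.5 to 65.0 M and HFD libraries 45.4 to 68.2 M. One count equals between 0.0147 and 0.0288 CPM (counts per M counts of the library). Between 30032 and 32062 identifiers had at least 1 read in a library. Replicate pairs of the same group correlated at r between 0.974 and 0.986 across genes on log2 CPM. They differed by at least 16.38 times the chi-square per degree of freedom of sampling noise, so no library was counted as a repeat of another in its group. Pairs from different groups were not compared in this way. Each title holds its own mouse number with suffix, and p-values measure the spread between mice.

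The test for single genes was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM normalization, robust dispersion and the default expression filter, which left 23622 genes. All 13 libraries entered 1 fit of the 4 groups with the sex letter as an additive term. The residual degrees of freedom were 8, the median prior degrees of freedom 3.69 and the common biological coefficient of variation 0.23. Adjusted p-values are Benjamini-Hochberg values over the 23622 genes, with a threshold of 0.05. The 6 comparisons were KO against control on each diet, the mean of both, the genotype by diet interaction, and HFD against chow in controls and in KO. Errors of log2 fold changes are standard errors (SE), and those of CPM are standard deviations (SD). Levels of Klf4 and of 4 neuropeptide genes were also compared by an exact two-sided permutation test of log2(CPM + 1).

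Gene lists for arcuate neuron types, glia, vessels, neighbouring tissue, and diet, stress and housekeeping pathways were fixed before the data were examined, as were the tests, the first set of other settings and the rule for named genes. Of these, 37 lists were tested with limma's camera at a preset correlation of 0.01 on log2 CPM (prior count 2), with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Member genes were also adjusted over the list alone. Klf4, Agrp, Npy, Pomc and Cartpt are always named. Because no comparison had 10 genes past the threshold, the rule named the 5 genes per direction with the smallest p and a mean log2 CPM of at least 1, and up to 4 members per list. Predicted genes, pseudogenes, ribosomal protein copies and X or Y sex genes were left out of that ranking. Hsd11b2 and Atp6v0d1 lie outside the rule and were chosen after their values were seen, as were genes that an alternative called when it called 5 or fewer. Some genes that the rule names are not reported here.

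Counts were simulated for 23622 genes with the same means and library sizes, drawn independently for each gene. At each fold 50 genes with a mean log2 CPM of at least 1 were changed. Of these the KO against control test on HFD recovered 36% at 1.5-fold, 80% at 2-fold and 94% at 4-fold. For KO against control on chow the shares were 32%, 54% and 98%. For HFD against chow in controls they were 30%, 78% and 94%, and in KO 30%, 72% and 96%. The simulated libraries held no differences in tissue content or batch, so these shares may not carry over to the real libraries.

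Other settings fixed at that point were RLE size factors, DESeq2 1.42.0, no filter on low counts, no sex term, only the 2 groups compared, limma voom with quality weights, 1 surrogate variable (sva 3.50.0), the estimated correlation, and each library left out in turn. Added after the data were seen were a sex term taken from the reads, pituitary and meningeal list means as covariates, removal of each library's trend with transcript length, and leaving out 2 doubted libraries in every comparison, singly and together. Exon-level counts were not analysed here, so the deleted part of Klf4 was not measured apart from the rest of the gene.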

Results

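RNA was counted in arcuate nucleus tissue from 13 mice to compare deletion of Klf4 in Agrp-expressing cells with control littermates on chow and on HFD. Klf4 encodes a zinc-finger transcription factor, and AgRP neurons drive feeding. There were 3 KO and 4 control mice on HFD, and 3 KO and 3 control mice on chow, each sequenced as 1 library. Total counts ranged from 34.7 to 68.2 M per library. By sex letter there were 6 M and 7 F mice, with 1 M and 2 F in each KO group, 2 M and 2 F in the HFD controls, and 2 M and 1 F in the chow controls.

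Klf4 (ENSMUSG00000003032.8, chromosome 4, 55527143 to 55532466, minus strand) was read first, as a check of the labels. Its level in KO on HFD was 2.42, 5.50 and 5.75 CPM, and in the libraries labelled control on HFD 1.60, 5.47, 3.09 and 4.10 CPM. On chow it was 2.17, 3.07 and 2.72 CPM in KO and 3.21, 2.35 and 2.66 CPM in controls. The log2 fold change of KO against control was 0.24 ± 0.37 (SE) on HFD, with an edgeR adjusted p of 1, and -0.18 ± 0.41 on chow, with an adjusted p of 0.878. With 1 library left out the HFD value was 0.06 (without Control_HFD replicate 1) to 0.63 (without Control_HFD replicate 2). An exact two-sided permutation test gave p = 0.514 on HFD, where the smallest possible p is 0.0286, and p = 0.8 on chow, where it is 0.1. The Klf4 count did not separate the genotype labels. These are counts of the whole gene in whole tissue, so they do not measure the deletion in Agrp-expressing cells.

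Genes beside Agrp did separate them, with 1 exception. Hsd11b2 (ENSMUSG00000031891.6, chromosome 8, 105518755 to 105523988, plus strand) encodes the enzyme that inactivates corticosterone. Its level was 64.4 ± 3.7 CPM (SD, n = 6) over the KO libraries, with a range of 60.8 to 69.4. In 6 of the 7 libraries labelled control it was 0.339 to 1.57 CPM. The library labelled Control_HFD replicate 3 had 63.4 CPM. Atp6v0d1 (ENSMUSG00000013160.7, chromosome 8, 105524465 to 105566047, minus strand), a subunit of the vacuolar proton pump, lies between Hsd11b2 and Agrp, 0.7 kb from the annotated Agrp model. It was at 269 ± 14.4 CPM (SD, n = 6) in KO, 192 to 210 CPM in the same 6 control libraries and 274 CPM in the library labelled Control_HFD replicate 3. Both genes were chosen after their values were seen. Every KO library thus differs from the same 6 control libraries beside Agrp as well as by label. Any KO against control comparison below holds this difference together with the deletion, and they cannot be separated here. This library is kept in its labelled group below, and the number of genes that edgeR called without it is given for each comparison.

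The sex letter was checked in the same way. Xist, the RNA that silences 1 X chromosome in females, was at 0.692 CPM in the library labelled Control_Chow replicate 3, whose letter is F. It was at 38.8 to 64.2 CPM in the other 6 F libraries and 0.459 to 1.19 CPM in the 6 M libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 185 CPM in that library, against 0.0548 to 2.36 CPM in the other F libraries and 174 to 208 CPM in the M libraries. With the letters as given, the F against M test called 0 genes by edgeR, with 812 genes at an unadjusted p under 0.05, and 23 genes by DESeq2. With the term taken from the reads it called 13 genes, all on X or Y, with Xist at 6.08 ± 0.31. By the reads all 3 chow controls were M, while KO on chow held 1 M and 2 F, so sex and genotype are unevenly divided on chow.

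**Figure D1:**
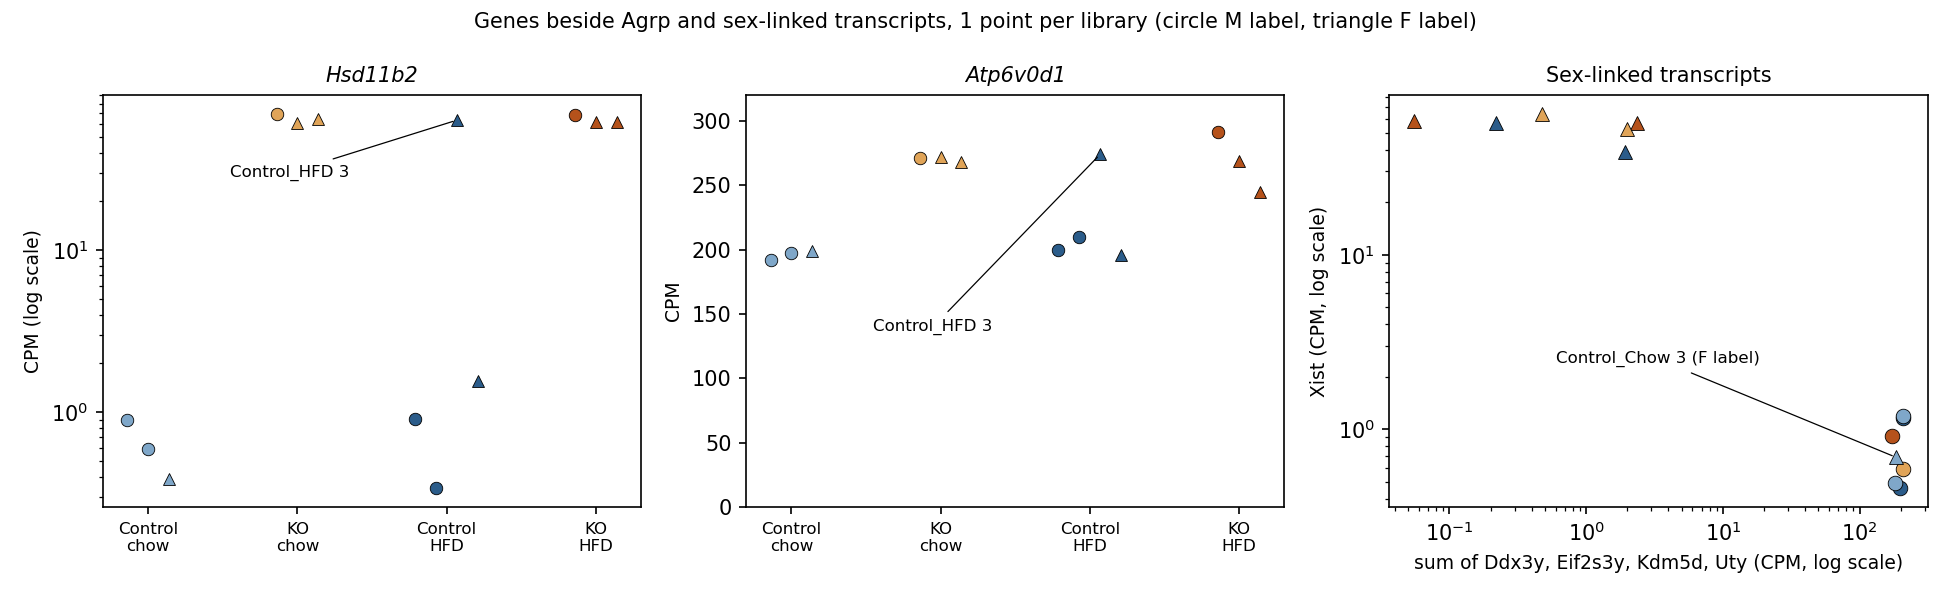
Hsd11b2 (log axis) and Atp6v0d1 in CPM for each library by group, and Xist against the sum of 4 Y-linked genes in CPM (both log axes), with circles for the M letter and triangles for F. The library labelled Control_HFD 3 lies with KO for both genes beside Agrp (63.4 and 274 CPM), and the library labelled Control_Chow 3 lies with the M libraries.

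Neuropeptide levels spread widely within groups. Agrp and Npy, the feeding-stimulating peptides of AgRP neurons, were at 35.7 ± 30.7 and 95.5 ± 61.0 CPM (SD, n = 3) in KO on HFD. In the libraries labelled control on HFD they were at 25.9 ± 23.9 and 82.4 ± 62.2 CPM (SD, n = 4). On chow Agrp was at 36.3 ± 19.1 CPM in KO and 11.5 ± 5.61 in controls (n = 3 each), and Npy at 122 ± 69.1 and 45.4 ± 28.0 CPM. Pomc, the precursor of a satiety peptide, was at 1180 ± 721 CPM in KO on chow and 304 ± 121 in controls. On HFD it was at 1430 ± 336 CPM in KO and 1140 ± 415 in the libraries labelled control. KO_Chow replicate 1, with the M letter, lay within the control range on chow for Agrp (14.4 CPM), Npy (46.4) and Pomc (367). The KO chow libraries with the F letter had Pomc at 1740 and 1440 CPM, and all chow controls were M by the reads. In KO on HFD Pomc was at 1290 CPM in the M library and 1190 and 1820 in the F libraries. In the libraries labelled control on HFD it was at 1290 and 1640 CPM in M and 681 and 960 in F. Cartpt, a feeding-suppressing peptide, was at 375 ± 105 CPM in KO on chow and 189 ± 34.3 in controls, with no overlap between the groups. The exact permutation p of Cartpt on chow was 0.1, the smallest that 3 against 3 mice allow, and those of Agrp, Npy and Pomc were 0.2, 0.2 and 0.3. On HFD the exact p for Agrp, Npy, Pomc and Cartpt was 0.829, 0.886, 0.4 and 0.571. Agrp lies on chromosome 8 (105566698 to 105637393), Npy on 6 (49822710 to 49829507), Pomc on 12 (3954951 to 3960642) and Cartpt on 13 (99898489 to 99901091).

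**Figure D2:**
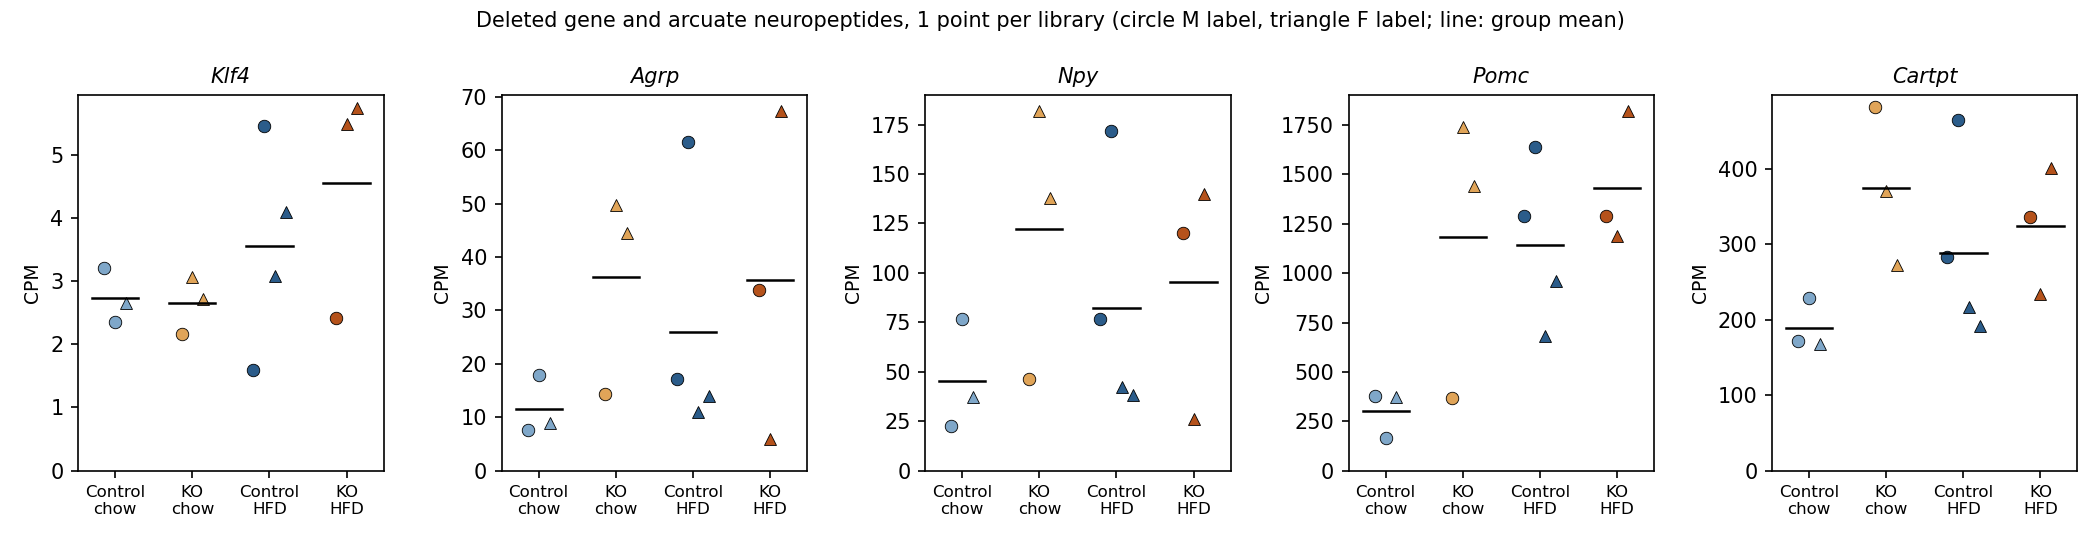
CPM of Klf4, Agrp, Npy, Pomc and Cartpt in each library by group, with the group mean as a line and the sex letter as the marker. Klf4 in KO and control libraries overlaps on both diets, and Cartpt on chow has no overlap between KO (mean 375 CPM) and control (mean 189 CPM).

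The comparison of KO with control on HFD asked what the deletion changes after HFD. Glucocorticoid-responsive genes were the only list whose camera call held with each library left out. Sgk1, a kinase induced by corticosterone, was at 72.8 ± 19.8 CPM (SD, n = 3) in KO and 46.5 ± 10.3 (n = 4) in the libraries labelled control, a log2 difference of 0.68 ± 0.17 (SE). Zbtb16, a transcription factor gene, differed by 0.62 ± 0.20, Fkbp5, a chaperone that dampens the glucocorticoid receptor, by 0.38 ± 0.13, and Tsc22d3, which encodes the protein GILZ, by 0.32 ± 0.13. Of the 11 members of the glucocorticoid response list 9 were higher and 2 lower, with a mean log2 fold change of 0.24. Adjusted over the list alone 3 members passed (Sgk1, Zbtb16 and Fkbp5), and 0 passed over all genes. Camera called the list (adjusted p = 4.1e-05), and its adjusted p was 0.55 with an estimated correlation. Without both doubted libraries its mean was 0.18.

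Other lists that camera called higher in KO on HFD were interferon response (mean log2 fold change 0.46, 13 of 14 members higher), oligodendrocyte myelin (0.45, 14 of 14), antigen presentation (0.27, 11 of 12), cytosolic ribosome (0.10, 28 of 30) and endoplasmic reticulum stress (0.09, 15 of 17). Among interferon-induced genes Oasl2 differed by 0.90 ± 0.49 and Isg15 by 0.76 ± 0.51. The myelin enzyme Cnp differed by 0.28 ± 0.26. GABA and glutamate transmission was called lower (-0.19, 14 of 15 members lower), with the vesicular glutamate transporter Slc17a7 at -1.26 ± 0.57. Each of these 6 lists had an adjusted p of 0.96 with an estimated correlation, and 0 of their members passed adjusted over the list alone. The myelin call ended without the library labelled Control_HFD replicate 3 (mean 0.10), as did those of antigen presentation (0.01) and GABA and glutamate transmission (-0.17). The interferon call ended without Control_HFD replicate 1 (0.30), and the ribosome and stress calls without that library (0.06 and 0.05) or without KO_HFD replicate 3 (0.04 each).

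Over all 23622 genes edgeR called 0 for KO against control on HFD, with 393 at an unadjusted p under 0.05 where chance gives 5% of the 23622 genes. DESeq2 also called 0 (397 at an unadjusted p under 0.05), as did voom (822). The smallest p among higher genes belonged to Pim3, a kinase (0.36 ± 0.09), Sgk1, N4bp1 (0.59 ± 0.17), Zbtb16 and Spcs3, a signal peptidase subunit (0.18 ± 0.06). Among lower genes it belonged to Scoc, a Golgi protein gene (-0.44 ± 0.09), Spag1 (-0.31 ± 0.09), the cation channel gene Trpc5 (-0.68 ± 0.20), Cpne2 (-0.33 ± 0.10) and AW551984 (-0.21 ± 0.07). All had an edgeR adjusted p of 1. Without the library labelled Control_HFD replicate 3, 1 gene passed, Hsd11b2 (6.03 ± 0.43, edgeR adjusted p 0.00335), against 2.44 ± 1.41 with it. That library is doubted because of its Hsd11b2 level, so this call is not separate evidence. Without it 335 genes had an unadjusted p under 0.05. That last count was 776 without Control_HFD replicate 2.

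On chow, KO was compared with control to find what the deletion changes without HFD. Cytosolic ribosome genes were all higher in KO, 30 of 30 members, by a mean log2 fold change of 0.34. Among them Rps27a differed by 0.40 ± 0.09, Rps3 by 0.32 ± 0.08, Rps23 by 0.45 ± 0.12 and Rps16 by 0.43 ± 0.12. Of the 30 members, 28 passed adjusted over the list alone and 0 over all genes. Camera called the list (adjusted p = 8.5e-18), and its adjusted p was 0.67 with an estimated correlation. Ribosomal transcripts are short, and the slope of a gene's deviation in log2 CPM on log2 transcript length was 0.026 to 0.039 in the chow controls and -0.036 to -0.001 in KO on chow. With each library's length trend removed the list's mean was 0.25, and camera still called it. Nuclear genes of the respiratory chain were higher in 18 of 23 members (mean 0.18), with Ndufa2 at 0.38 ± 0.10. That call ended without KO_Chow replicate 1 (mean 0.05), and the adjusted p was 0.71 with an estimated correlation.

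Of the 4 lists of arcuate neuron types, camera called 3 higher in KO on chow, and KNDy neuron was not called (mean 0.46, 6 of 8 members higher, adjusted p = 0.23). Th, the rate-limiting enzyme of dopamine synthesis, differed by 1.48 ± 0.38, the neuropeptide gene Gal by 0.90 ± 0.28, Ghrh, the growth hormone releasing hormone gene, by 0.98 ± 0.35 and Sst, the somatostatin gene, by 0.71 ± 0.29. Of the 9 dopamine and GHRH neuron genes 8 were higher (mean 0.70), 2 passed adjusted over the list alone (Th and Gal), and the adjusted p was 0.67 with an estimated correlation. POMC neuron genes were higher in 8 of 9 members (mean 0.63), and Cartpt passed adjusted over the list alone, with an adjusted p of 0.67 for the list with an estimated correlation. AgRP neuron genes were higher in 9 of 12 (mean 0.71), with Asb4 at 0.84 ± 0.26 and the protease gene Corin at 2.47 ± 1.04, 0 past adjustment over the list alone, and an adjusted p of 0.71 with an estimated correlation. Without the library labelled Control_Chow replicate 3 the POMC and AgRP neuron calls ended (means 0.56 and 0.54), as they did without KO_Chow replicate 2 (0.57 and 0.53) or KO_Chow replicate 3 (0.56 and 0.65), and the POMC call also without Control_Chow replicate 1 (0.64). The dopamine and GHRH call held with each library left out. All chow controls were M by the reads, and with the sex term from the reads camera called fewer lists on chow.

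Camera also called lists of cells that line the ventricle beside the arcuate nucleus. Ependymal cilia genes were higher in KO on chow in 10 of 10 members (mean 1.46), with Rsph1, a cilium spoke gene, at 1.12 ± 0.31 past adjustment over the list alone. Tanycyte genes were higher in 11 of 12 (mean 0.92), with Crym at 1.01 ± 0.54 and Lhx2 at 1.11 ± 0.61. Microglia genes were higher in 13 of 14 (mean 0.36), among them Trem2, a lipid receptor, at 0.64 ± 0.21, and antigen presentation genes in 8 of 12 (mean 0.32). Lower lists were synaptic vesicle (-0.20, 12 of 14 members lower; Unc13a -0.30 ± 0.12), cholesterol synthesis (-0.15, 17 of 20; Hsd17b7 -0.35 ± 0.13) and circadian clock (-0.12, 12 of 16; Cry2 -0.18 ± 0.05). The adjusted p of these lists was 0.71 with an estimated correlation, and 0.67 for the clock list. Without the library labelled Control_Chow replicate 3 the calls of the tanycyte (0.81), antigen presentation (-0.18), synaptic vesicle (-0.09), cholesterol (-0.05) and clock (-0.13) lists ended, while the ependymal (1.37) and microglia (0.29) calls held. The microglia call ended with both doubted libraries left out (0.20).

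For single genes on chow edgeR called 0, with a smallest adjusted p of 0.263, while 3050 genes had an unadjusted p under 0.05 (1615 higher and 1435 lower) where chance gives 5% of the 23622 genes. DESeq2 called 344 genes, 152 higher and 192 lower, and voom called 0 (3419 at an unadjusted p under 0.05). By smallest p the higher genes were Tmsb4x, an actin-binding peptide (0.42 ± 0.08; 599 ± 26.5 CPM in KO and 438 ± 22.9 in controls, SD, n = 3 each), Cotl1, another actin-binding gene (0.86 ± 0.17), Dbi, which binds acyl-CoA (0.81 ± 0.16), Trappc2l (0.43 ± 0.08) and Sec11c, a signal peptidase subunit (0.31 ± 0.06). The lower genes were Fam171a2 (-0.52 ± 0.08; 33.2 ± 0.6 CPM in KO and 47.2 ± 2.61 in controls), Amot, a junction protein gene (-0.77 ± 0.13), Mical2 (-0.46 ± 0.08), Eml2 (-0.41 ± 0.07) and Adarb1, an RNA-editing enzyme (-0.72 ± 0.13). These 10 had an edgeR adjusted p of 0.263 and all passed by DESeq2, as did Pomc and Cartpt. DESeq2 on all libraries also called Hsd11b2 and Atp6v0d1 (DESeq2 adjusted p 0.00571 and 0.0383). With only the 2 chow groups in the fit edgeR called Hsd11b2 alone (adjusted p 6.92e-05). Without the library labelled Control_HFD replicate 3, which is in neither chow group but enters the same fit, edgeR called 1 gene, Hsd11b2 (adjusted p 0.00281), with 2944 at an unadjusted p under 0.05. Without KO_Chow replicate 1 it called 1 gene, Dbi, and without the library labelled Control_Chow replicate 3 it called 0, with 2050 at an unadjusted p under 0.05.

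The mean of the KO differences on both diets asked what the deletion changes whatever the diet. Ribosome genes were higher in 30 of 30 members (mean 0.22), and 27 passed adjusted over the list alone. Dopamine and GHRH neuron genes were higher in 7 of 9 (mean 0.39), with Gal at 0.70 ± 0.19 and Th at 0.92 ± 0.26 past adjustment over the list alone. In the POMC neuron list (mean 0.42) Cartpt at 0.72 ± 0.19 and Pcsk1, a prohormone convertase, at 0.25 ± 0.07 passed it. Camera called 15 lists, 11 higher and 4 lower, and all lost their call with an estimated correlation, at adjusted p from 0.66 to 0.70. The others higher were microglia (0.22), oligodendrocyte myelin (0.49), interferon response (0.45), antigen presentation (0.29), tanycyte (0.61), ependymal cilia (0.61), nuclear respiratory chain (0.10) and endoplasmic reticulum stress (0.10), and those lower were synaptic vesicle (-0.14), GABA and glutamate transmission (-0.17), cholesterol synthesis (-0.09) and circadian clock (-0.07). With both doubted libraries left out 7 lists were called. The ribosome and dopamine and GHRH calls held under every left-out library, and the interferon mean was 0.02 with both doubted libraries left out.

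Single genes for the mean of both diets numbered 0 past the threshold by edgeR (smallest adjusted p 0.437), with 2245 at an unadjusted p under 0.05. DESeq2 called 52 genes, 27 higher and 25 lower, and voom 0 (2892 at an unadjusted p under 0.05). The smallest p belonged to Tmsb4x (0.29 ± 0.05), Sec11c (0.23 ± 0.04), Trappc2l (0.29 ± 0.06), Mrps28, a mitochondrial ribosome gene (0.26 ± 0.05), and the noncoding RNA Gas5 (0.31 ± 0.06), and among lower genes to Prrg3 (-0.42 ± 0.07), Mical2 (-0.26 ± 0.05), Amot (-0.43 ± 0.09), Sptan1, a spectrin (-0.36 ± 0.08), and the ubiquitin ligase gene Nedd4l (-0.32 ± 0.07). Without the library labelled Control_HFD replicate 3, edgeR called 2 genes, Hsd11b2 (6.35 ± 0.32, adjusted p 0.000142) and Atp6v0d1 (0.45 ± 0.05, adjusted p 0.0337), with 1930 at an unadjusted p under 0.05. The levels of both genes are why this library is doubted, so these calls are not separate evidence. With both doubted libraries left out only Hsd11b2 passed.

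The interaction asked whether the KO difference was larger or smaller on HFD than on chow. Glucocorticoid-responsive genes had a more positive KO difference on HFD, by a mean of 0.36 over 11 members, 9 of them in that direction. On chow itself 8 of the 11 were lower in KO and 3 higher (mean -0.12), a difference that camera did not call (adjusted p = 0.23, and 0.71 with an estimated correlation). Adjusted over the list alone 5 passed there: Fkbp5 (-0.45 ± 0.14), Zbtb16 (-0.59 ± 0.22) and Ddit4 (-0.40 ± 0.15) lower, and the metallothionein genes Mt2 (0.71 ± 0.15) and Mt1 (0.44 ± 0.11) higher, and fry's test for change in either direction gave an adjusted p of 0.00039. For the interaction 5 members passed adjusted over the list alone: Fkbp5 (0.83 ± 0.19), Zbtb16 (1.21 ± 0.29), Sgk1 (0.90 ± 0.25), Ddit4, a stress-induced mTOR inhibitor (0.62 ± 0.20), and in the other direction Mt2 (-0.55 ± 0.19). The same fry test gave the interaction an adjusted p of 0.0003. More negative on HFD were cytosolic ribosome (-0.24, 30 of 30 members), ependymal cilia (-1.70, 10 of 10), dopamine and GHRH neuron (-0.62, 9 of 9), AgRP neuron (-0.57, 9 of 12), microglia (-0.27, 13 of 14) and nuclear respiratory chain (-0.15, 21 of 23). All 7 lists had an adjusted p of 0.91 with an estimated correlation. The ribosome and ependymal calls held with each library left out. The glucocorticoid call ended without Control_Chow replicate 2 (0.30).

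EdgeR called 0 genes for the interaction, with 1205 at an unadjusted p under 0.05, and voom called 0 (1719). DESeq2 called 6, among them Fam171a2, Eml2, Btaf1 and Fam78b. The smallest p among genes more positive on HFD belonged to Fam171a2 (0.59 ± 0.11), Eml2 (0.50 ± 0.09), Btaf1 (1.19 ± 0.25), Fam78b (1.03 ± 0.22) and Fkbp5. Among those more negative it belonged to the cilium genes Cfap45 (-0.93 ± 0.21) and Spag6l (-1.21 ± 0.30), and to Cdkl4 (-0.64 ± 0.15), Lsm4 (-0.47 ± 0.11) and Cotl1 (-0.90 ± 0.22). All 10 had an edgeR adjusted p of 0.909. With the library labelled Control_HFD replicate 3 left out edgeR called 0, with 1093 at an unadjusted p under 0.05.

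HFD was compared with chow in the libraries labelled control. Diet cannot be separated here from any batch that follows the mouse numbers. By the reads all chow controls were M, while the HFD controls were 2 M and 2 F. Microglial genes were higher on HFD in 14 of 14 members, by a mean log2 fold change of 0.53. The complement genes C1qc and C1qb differed by 0.73 ± 0.18 and 0.69 ± 0.18, and the adaptor gene Tyrobp by 0.74 ± 0.20. Adjusted over the list alone 10 of the 14 passed, and 0 over all genes. Antigen presentation (0.79, 12 of 12 members; B2m 0.85 ± 0.30), interferon response (0.73, 12 of 14; Ifi27 0.79 ± 0.29), inflammatory signalling (0.50, 11 of 14; Ccl2 2.27 ± 0.75), immediate early genes (0.32, 14 of 18; Junb 0.54 ± 0.15), cytosolic ribosome (0.23, 30 of 30) and nuclear respiratory chain (0.14, 19 of 23) were higher. Ccl2 lay near the floor, at 0 to 0.115 CPM on chow and 0.168 to 0.728 CPM on HFD. The pituitary and leptomeningeal fibroblast lists were at 2.59 and 0.54, without a camera call (adjusted p = 0.34 and 0.19). Cholesterol synthesis was lower (-0.17, 18 of 20; Cyp51 -0.25 ± 0.08). These 8 lists had an adjusted p of 0.75 with an estimated correlation. Without the library labelled Control_Chow replicate 3 the calls of antigen presentation (0.39), interferon response (0.33), inflammatory signalling (0.45) and cholesterol synthesis (-0.08) ended. Those of microglia (0.47), ribosome (0.26) and nuclear respiratory chain held with each library left out. Without Control_HFD replicate 2 the interferon mean was 0.22 and the inflammatory mean -0.07, and neither was called.

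For diet in controls edgeR called 0 genes, with 1905 at an unadjusted p under 0.05, and voom 0 (1967). DESeq2 called 46 genes, 19 higher and 27 lower. The smallest p belonged to Cachd1, a calcium channel regulator (-0.69 ± 0.10; 37.3 ± 4.18 CPM on HFD, n = 4, and 58.9 ± 6.43 on chow, n = 3; edgeR adjusted p 0.158), the metabotropic glutamate receptor gene Grm4 (-0.72 ± 0.13), Dscam (-0.66 ± 0.13) and the neurofilament gene Nefh (-0.47 ± 0.10). Higher on HFD were the metallothionein genes Mt2 (0.78 ± 0.14) and Mt1 (0.51 ± 0.10), Tmsb4x (0.40 ± 0.07), the cholecystokinin receptor gene Cckar (0.66 ± 0.13) and Lsm4 (0.39 ± 0.08). Pomc differed by 1.92 ± 0.54 (edgeR adjusted p 0.563). With the library labelled Control_HFD replicate 3 left out edgeR called 0, with 2220 at an unadjusted p under 0.05. That last count was 1068 without Control_HFD replicate 2. Without Control_Chow replicate 2, edgeR called Gm45774 and Mt2, and without the low-count filter it called Cachd1, Gm45774, Mt2, Gja3 and Grm4. This comparison and that of KO with control on chow share the 3 chow control libraries, so genes and lists that appear in both are not independent.

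In KO mice, HFD against chow gave the clearest glucocorticoid difference. Zbtb16 was at 7.57 ± 1.49 CPM on HFD and 3.87 ± 0.889 on chow (SD, n = 3 each), a log2 difference of 0.97 ± 0.21, and Sgk1 differed by 0.84 ± 0.18, Fkbp5 by 0.50 ± 0.14 and Ddit4 by 0.42 ± 0.14. All 11 members of the list were higher (mean 0.40), these 4 passed adjusted over the list alone, and the list's adjusted p was 8.2e-08 by camera and 0.19 with an estimated correlation. Interferon response was higher in 14 of 14 members (0.76; Isg15 1.25 ± 0.55), endothelial in 10 of 11 (0.44; Pecam1 0.62 ± 0.26) and ependymal cilia lower in 9 of 10 (-1.31; Pifo -1.03 ± 0.33), each with an adjusted p of 0.77 with an estimated correlation. The calls of these 4 lists held with each library left out. Also called higher, at adjusted p of 0.77 or 0.78 with an estimated correlation, were microglia (0.26), mitochondrial respiratory chain (0.18), antigen presentation (0.74), leptomeningeal fibroblast (1.39), oligodendrocyte precursor (0.31), oligodendrocyte myelin (0.26) and pituitary (2.87, 7 of 8 members higher). The microglia, antigen presentation and myelin calls ended without KO_Chow replicate 1 (0.12, 0.56 and -0.23), and the pituitary call without KO_HFD replicate 3 (2.03) or KO_HFD replicate 1 (2.85).

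Single genes for diet in KO numbered 0 by edgeR, with 957 at an unadjusted p under 0.05, and 0 by voom (1597). DESeq2 called 8 genes, 4 higher and 4 lower. By smallest p the higher genes were Eml2 (0.33 ± 0.07), Btaf1 (0.88 ± 0.18), Zbtb16, Sh3tc1 (1.09 ± 0.24) and Sgk1, and the lower ones Cfap45 (-0.88 ± 0.15), Ppp1r32 (-1.56 ± 0.32), Rgs22 (-2.12 ± 0.45), Spag6l (-0.96 ± 0.22) and Cdkl4 (-0.48 ± 0.11). All 10 had an edgeR adjusted p of 0.984. With the library labelled Control_HFD replicate 3 left out edgeR called 0, with 1022 at an unadjusted p under 0.05.

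**Figure D3:**
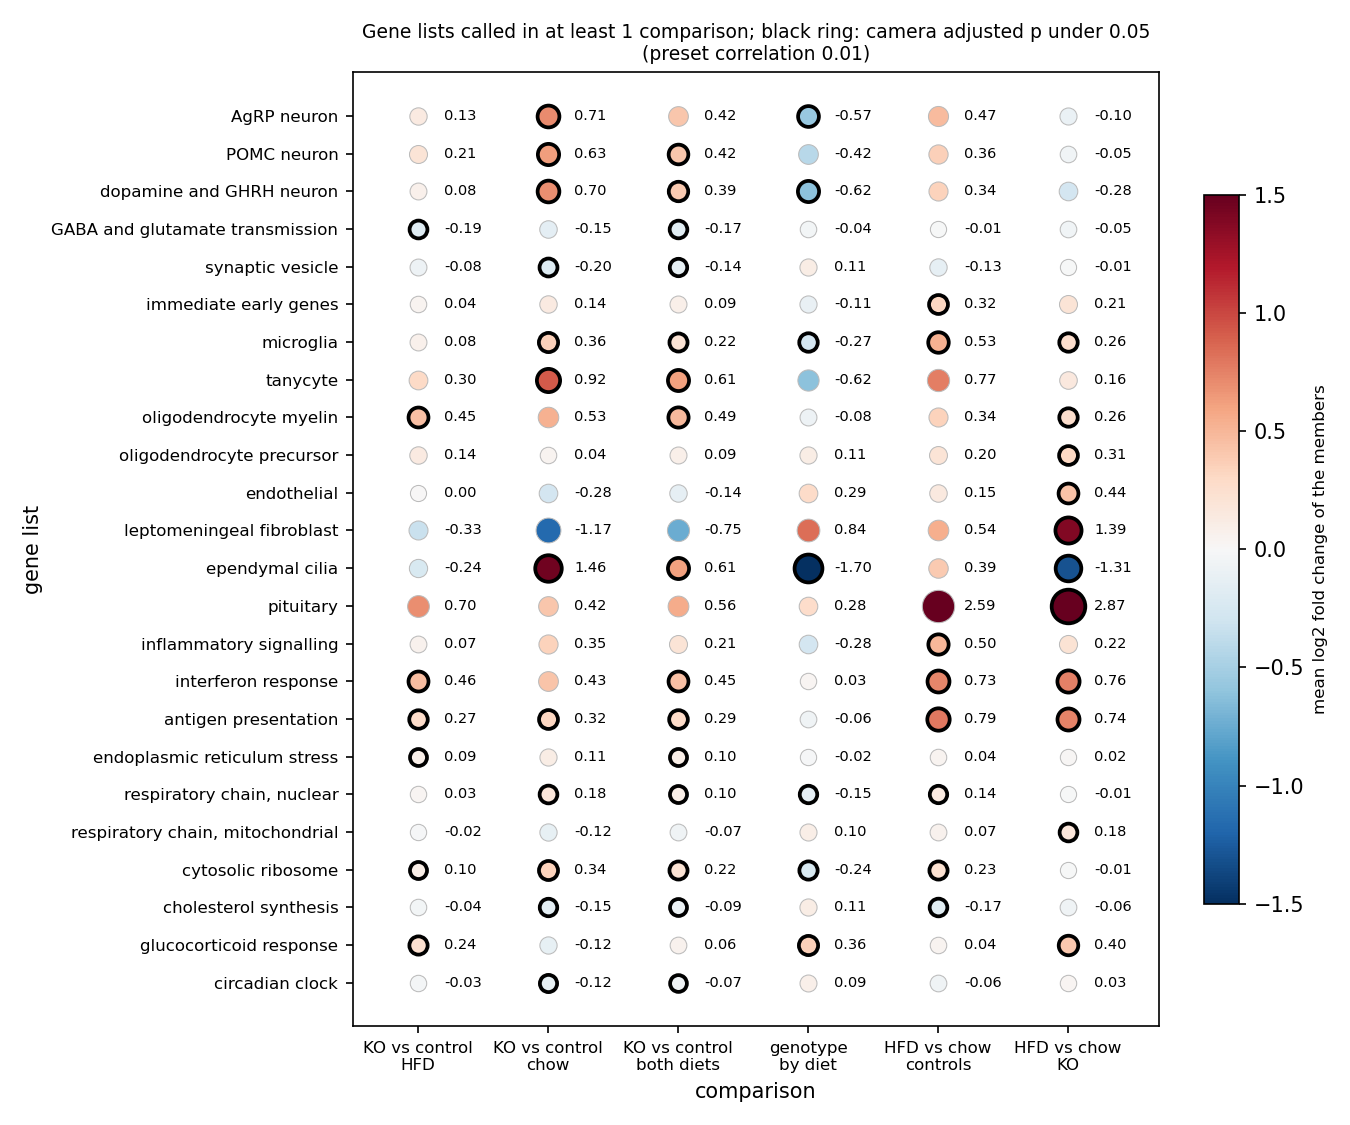
Mean log2 fold change of the members (number and colour) of each gene list called by camera in at least 1 of the 6 comparisons, with a black ring where the adjusted p at the preset correlation was under 0.05. Cytosolic ribosome has its highest value for KO against control on chow (0.34), and glucocorticoid response is at 0.24 for KO on HFD and 0.40 for diet in KO.

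The content of neighbouring tissue differed between libraries. Between the lowest and the highest of the 13 libraries, the level of the pituitary list spanned 48.1-fold, leptomeningeal fibroblast 17.6-fold, ependymal cilia 7.83-fold, tanycyte 7.23-fold and neighbouring hypothalamic nuclei 6.91-fold. Within groups, the SD of the pituitary list in log2 CPM was 0.22 in chow controls, 0.79 in KO on chow, 2.14 in the libraries labelled control on HFD and 2.13 in KO on HFD. The glucocorticoid list spanned 1.52-fold and the cytosolic ribosome list 1.54-fold. On the first principal component of log2 CPM, which held 29.5% of the variation, KO_HFD replicate 3 (62.5) and the library labelled Control_Chow replicate 3 (-51.9) lay farthest apart.

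**Figure D4:**
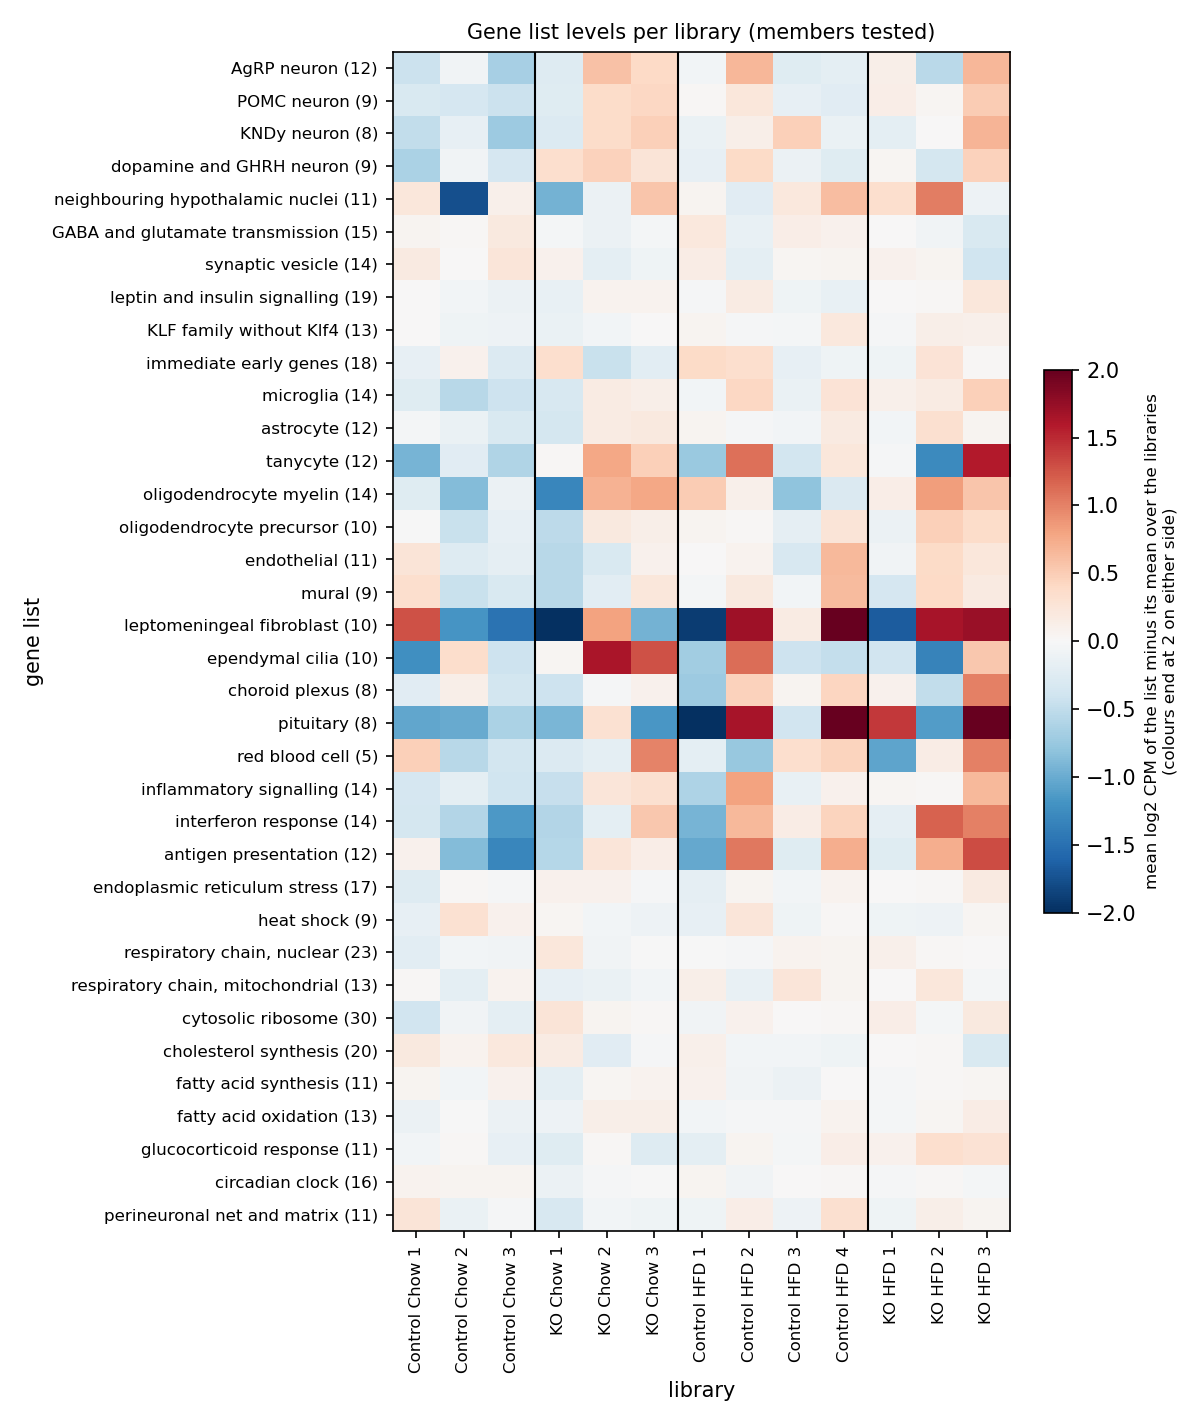
Mean log2 CPM of each gene list per library, less its mean over the 13 libraries, with colours ending at 2 on either side and the number of tested members in brackets. Over the 13 libraries pituitary spans 48.1-fold and leptomeningeal fibroblast 17.6-fold.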

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

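Among the tests in this part, the 3 on the library labelled Control_HFD replicate 3, those of the sex of the libraries, of the length trend and of endothelial and oligodendrocyte content, of pituitary and meningeal covariates, and those without the doubted libraries were chosen only after the results they address had been seen.

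In the 4 libraries labelled control on HFD, 88 values were tested for 1 library far from the other 3 (a gap of more than 0.829 of the range), and 5 were (5.68%, where chance gives about 1 in 20 groups, 5%), of which 4 are given here. Control_HFD replicate 2 was far from the others for Agrp (61.6 CPM, against 11 to 17.1) and for the ependymal cilia list (mean log2 CPM 3.15, against 1.34 to 1.62). Control_HFD replicate 4 was far for Sh3tc1 (4.62 CPM, against 2.21 to 2.41). The library labelled Control_HFD replicate 3 was far for Hsd11b2 (63.4 CPM, against 0.339 to 1.57). Hsd11b2 and Atp6v0d1 were put among the 88 after their values were seen, so this flag was fixed in advance. Many of the other genes were named for a small p in comparisons that use these libraries. The share of 5.68% can therefore not be read against the 5% of chance. Groups of 3 libraries were not tested in this way.

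The KO difference was not the same on both diets by the interaction test for 7 lists: AgRP neuron (-0.57), dopamine and GHRH neuron (-0.62), microglia (-0.27), ependymal cilia (-1.70), nuclear respiratory chain (-0.15), cytosolic ribosome (-0.24) and glucocorticoid response (0.36). None was called with an estimated correlation (adjusted p = 0.91 each). The AgRP neuron call ended when any 1 of 8 libraries was left out, with a mean of -0.24 without Control_HFD replicate 2, and the microglia call likewise for 8, with -0.11 without that library. The dopamine and GHRH call ended without KO_HFD replicate 2 (-0.45), Control_HFD replicate 2 (-0.44), KO_Chow replicate 2 (-0.54) or Control_Chow replicate 1 (-0.49). The respiratory call ended without KO_Chow replicate 1 (-0.04) or Control_Chow replicate 1 (-0.10), and the glucocorticoid call without Control_Chow replicate 2 (0.30).

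The library labelled Control_HFD replicate 3, whose title shares a mouse number with KO_HFD replicate 2 under another suffix, has Hsd11b2 at the level of the 6 KO libraries. A swap with another of the 13 libraries would leave a KO library at the control level, and 0 were. A mixture of KO and control tissue would lie between the levels, and at 63.4 CPM Hsd11b2 lies within the KO range of 60.8 to 69.4, though a small share of control tissue is not excluded. Atp6v0d1, the next gene toward Agrp, is also at the KO level there (274 CPM, against 192 to 210 in the other 6 control libraries), so a candidate explanation is that this mouse carried the altered Agrp locus, or a transgene with sequence around Agrp, that the KO mice carry. The values cannot tell a wrong genotype label from a control that carries Cre without losing Klf4, since neither the controls' Cre status nor the Agrp-Cre line is given, and no biological explanation was tested.

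On chow, 3050 genes had an unadjusted p under 0.05 by edgeR for KO against control, where chance gives 5% of the 23622 genes. Removing each library's length trend left 2367 and an additive sex term from the reads left 2649, so neither of these terms accounts for the whole excess. Without the library labelled Control_Chow replicate 3 the count was 2050. By the reads all 3 chow controls were M, against 1 M and 2 F in KO on chow. The sex term assumes the same sex difference in every group, so it does not settle sex within chow. Tissue content stays open, since the chow log2 fold changes correlated with the leading axis among the 7 HFD libraries at r = 0.22. That axis held 35.9% of their variation, and r lay between the bounds of 0.1 and 0.3 set beforehand. The count did not fall with pituitary and meningeal covariates (3496) or 1 surrogate variable (3393), but these do not settle the question. Camera called neither covariate list on chow, and the surrogate variable was estimated with the groups kept in its model. The ependymal cilia and tanycyte lists, which camera called on chow, were not used as covariates. Of the 10 splits of the 6 chow libraries 1, the real one, gave as many genes (highest other 1754), and 1 gave as many past the threshold by DESeq2 (344, highest other 30), and 10 splits are too few for a share under 0.05. On chow Hsd11b2, beside Agrp, was at 60.8 to 69.4 CPM in KO and 0.387 to 0.895 CPM in controls. A response to the deletion, the uneven sex of the chow groups and a difference in dissection may all contribute. So may whatever the KO mice carry beside Agrp, and these cannot be told apart here.

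In KO on HFD the glucocorticoid response list was higher by a mean log2 of 0.24 than in the libraries labelled control on HFD. With endothelial and oligodendrocyte list means as covariates the mean was 0.26, with the length trend removed it was 0.24, and with 1 HFD library left out it was 0.20 at the lowest (without KO_HFD replicate 2 or Control_HFD replicate 1) and 0.30 at the highest, so none of these accounts for it. Without both doubted libraries it was 0.18, and on chow the list's mean KO difference was -0.12. The call rests on the preset correlation (adjusted p = 0.55 with an estimated one). Hsd11b2, whose enzyme inactivates corticosterone, was at 61.6 to 68.5 CPM in KO on HFD. It was at 0.339 to 1.57 CPM in the HFD controls other than the library labelled Control_HFD replicate 3, which had 63.4. Hsd11b2 was also higher in KO on chow. A stronger corticosterone response in KO on HFD may account for the list's difference. Stress or the hour at collection, which the labels do not give, may too. So may the Hsd11b2 difference, and none of these was tested.

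For genes past the adjusted threshold by edgeR the real count was 0 in all 6 comparisons, so every split necessarily gives as many, and these counts decide nothing about chance. For KO against control on HFD all 35 splits gave as many (highest other 1), for the mean of both diets all 60 (highest other 2), for the interaction all 60 (highest other 9) and for diet in controls all 35 (highest other 181). The 35 are every possible split. The 60 are the real split and others drawn at random from a larger number, so their shares and highest values are not exact. The split with 181 genes set Control_Chow replicate 2, Control_HFD replicate 1 and the libraries labelled Control_HFD replicate 3 and Control_Chow replicate 3 against the other 3, which points to a structure of the samples other than diet. For KO against control on chow and for diet in KO the 10 splits (10 of 10 as large, real count 0, highest other 0) are too few for a share under 0.05. At an unadjusted p under 0.05, 33 of 35 splits gave as many genes as the real one for KO on HFD. It was 12 of 35 for diet in controls (1905, highest other 3366) and 5 of 60 for the mean (2245, highest other 4030). For the interaction it was 23 of 60 and for diet in KO 3 of 10, the real split counted each time.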

How the results depend on the processing

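Chosen only after the data were seen were the tests with a sex term from the reads, with pituitary and meningeal covariates, with the length trend removed and with both doubted libraries left out.

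RLE size factors, no sex term and the length trend removed kept all 88 single-gene values on the same side of the threshold and in the same direction, and DESeq2 kept 43 and moved 45 past it. Genes past the threshold, 0 by edgeR in each comparison, were 344 by DESeq2 for KO on chow, 52 for the mean of both diets, 6 for the interaction, 46 for diet in controls, 8 for diet in KO and 23 for F against M. Without the low-count filter they were 1 for KO on chow and 5 for diet in controls. With only the 2 groups compared they were 1 for KO on chow, Hsd11b2, and with the sex term from reads 13 for F against M. With both doubted libraries left out they were 1 for KO on HFD, 1 for KO on chow and 1 for the mean, Hsd11b2 each time. The level of Hsd11b2 is itself why 1 of these libraries is doubted. Leaving out 1 library gave 0 to 1 for KO on HFD, 0 to 1 for KO on chow, 0 to 2 for the mean, 0 to 0 for the interaction, 0 to 2 for diet in controls and 0 to 0 for diet in KO.

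Lists called with an estimated correlation were 0 in KO on HFD, 0 on chow, 0 for the mean, 0 for the interaction, 0 for diet in controls and 0 for diet in KO, against 7, 12, 15, 7, 8 and 11. With covariates 4 lists were called for KO on HFD. For KO on chow 6 were called with 1 surrogate variable, 7 with the sex term from reads and 6 with both doubted libraries left out, which left 7 for the mean and 4 for diet in controls. Leaving out 1 library gave 2 (without Control_HFD replicate 1) to 14 (without KO_HFD replicate 2) for KO on HFD, 6 (without KO_Chow replicate 2) to 13 for KO on chow, 7 (without Control_Chow replicate 3) to 18 for the mean, 4 to 11 for the interaction, 4 (without Control_Chow replicate 3) to 12 for diet in controls and 9 to 13 for diet in KO.

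Some values that had not passed for single genes changed sign. In KO on HFD, Agrp (0.62) was -0.08 with voom weights, -0.21 with covariates and -0.47 (without KO_HFD replicate 3) to 1.34 with 1 library left out. Npy (0.38) was -0.03, -0.23 and -0.24 to 0.87 under the same settings. Pomc (0.24) was -0.09 without both doubted libraries and -0.08 (without Control_HFD replicate 3) to 0.49 with 1 left out. Klf4 on chow (-0.18) was 0.01 with covariates and -0.39 to 0.00 with 1 left out. For the mean Klf4 (0.03) was -0.08 with 1 surrogate variable, -0.08 with the sex term from reads, -0.24 without both doubted libraries and -0.09 to 0.25 with 1 left out. For diet in controls Klf4 (0.32) was -0.24 with 1 surrogate variable, -0.06 with covariates and -0.24 to 0.58 with 1 left out. For the result Agrp, HFD against chow in KO (-0.08), values were 0.16 with only the 2 groups and -1.49 to 0.44 with 1 left out, and Pomc there (0.33) was -0.20 to 0.68.

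Antigen presentation changed sign most often. Without both doubted libraries it was -0.17 for KO on HFD, -0.36 on chow and -0.26 for the mean, and with 1 library left out -0.09 to 0.69, -0.18 to 0.94 and -0.02 to 0.60. For diet in KO it was -0.05 with 1 surrogate variable and -0.09 with covariates. Inflammatory signalling for diet in controls was -0.07 to 0.69, and for diet in KO oligodendrocyte myelin was -0.23 to 0.53 with 1 library left out and leptomeningeal fibroblast -0.03 with covariates, which include that list. Of the 60 list calls, 1 surrogate variable ended 20 and reversed 1, and both doubted libraries left out ended 25 and reversed 3. Apart from that last covariate, the cause was not tested for any of these changes.

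No paired analysis was possible because only 1 mouse number in the titles, that of KO_HFD replicate 2 and the library labelled Control_HFD replicate 3, occurs in 2 groups, with different suffixes, and what it marks is not given in the labels. Depth, 34.7 to 68.2 M counts, is lowest in the chow controls.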

Other observations

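Lists that camera called in no comparison included leptin and insulin signalling, with a mean log2 fold change of 0.10 for KO on HFD (14 of 19 members higher) and 0.05 on chow. The other KLF genes were at 0.00 and -0.03, KNDy neuron genes at 0.04 and 0.46, astrocyte genes at 0.04 and 0.11, heat shock genes at -0.06 and -0.12, and perineuronal net and matrix genes at -0.07 and -0.27. Neighbouring hypothalamic nuclei were at 0.01 and 0.11, mural cells at -0.17 and -0.21, choroid plexus at 0.01 and -0.01, red blood cell genes at 0.04 and 0.00, fatty acid synthesis at 0.02 and -0.07, and fatty acid oxidation at 0.04 and 0.09. The X and Y sex genes were at -0.27 and -3.07. On chow 1 member passed adjusted over the list alone in each of leptin and insulin signalling, heat shock and fatty acid synthesis. A small mean therefore does not show that no member differed.

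In some lists without a call the mean and the camera direction differed in sign. The means come from the edgeR fit of counts and camera was run on log2 CPM. The AgRP neuron list in KO on HFD had a mean of 0.13 with camera pointing lower, and the pituitary list in KO on chow had 0.42 with camera pointing lower.

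Ranked by the gap in log2 CPM between the 3 KO and the 3 control libraries on chow, Hsd11b2 came first of 23622 genes with a gap of 6.02. The next genes were Gja3 (1.82), Hcar2 (1.45), Frzb (1.38) and Stat4 (1.36). These genes were chosen after their values were seen.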
